A study of Homo sapiens with 12 samples.

How the data were processed

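RNA from 12 cell samples was measured on 1-colour GeneChip human arrays of the U133 A 2.0 type with biotin-labelled targets, 3 arrays for each of 4 groups: non-transduced endothelial progenitor cells from whole blood (EPC), cells after 2 weeks of doxycycline-induced MYOCD expression (iSMC-2w), cells after those 2 weeks and 2 further weeks without doxycycline (iSMC-4w), and primary umbilical smooth muscle cells (UASMC). The series text places the UASMC in the umbilical artery and their sample titles in the umbilical aorta, while a source characteristic of these samples names whole blood, and the sources do not settle it. The deposited values are log2 expression summaries per probe set that the authors made with RMA, Affymetrix Expression Console and Partek, per the submitters' processing notes, which give no versions, order or settings. The table holds 22277 probe sets. Column medians lay between 7.66 and 7.71 log2, and the sorted columns differed by at most 0.263 at any rank, so the arrays had been brought to nearly the same distribution before deposit.

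Of the probe sets, 62 are Affymetrix controls, 19070 are listed with 1 gene symbol, 1043 with several and 2164 with none. Of the 19070, 19058 were matched by Entrez identifier to RefSeq genes and 12 kept the listed symbol. Leaving out 85 for genes that differ between donors or by sex and 6 controls listed with a gene, 18979 entered the gene step. Each of the 11914 genes entering the tests was represented by its probe set with the highest mean over the 12 arrays, and 4291 genes had more than 1. No filter on signal was applied, and genes near the background of the array are not marked as such by the source used. With the highest value of the TrpnX control probe sets, 5.20 log2, as a guide added after the data were seen, 214 of the 7809 genes called in iSMC-2w minus EPC had both group means at or under it and 230 had 1.

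The fits used R 4.3.3 with limma 3.58.1. A linear model with 1 mean per group was fitted to all 12 arrays (8 residual degrees of freedom), with moderated t-tests for 6 comparisons. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold, and the count at 2-fold or more is given beside it. Errors of differences are standard errors from limma, with a median over genes of 0.0791 log2, and errors of group means are SDs of 3 arrays. Lists of genes were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the 23 lists of a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move 1 way on balance without comparing them with other genes, were alternatives. The lists were smooth muscle contractile, smooth muscle channels and receptors, endothelial, Notch and arterial-venous, cardiac and skeletal sarcomere, myogenic and cardiac regulators, fibrillar matrix and elastic fibre, basement membrane, fibroblast and pericyte, blood cell, epithelial, TGF-beta response, serum response immediate early, cell cycle, p53 and senescence, interferon response, NF-kB and inflammatory cytokines, ATF4 and unfolded protein response, nuclear genes of the mitochondrial respiratory chain, cholesterol synthesis, glycolysis and hypoxia, HOX genes and ribosomal proteins. The comparisons, tests, lists and the rule for naming genes were set before the data were examined. By that rule the text names called genes with the largest rise or fall whose 3 arrays in 1 group all lie above those of the other (up to 6 each way, or 3 in UASMC minus EPC and iSMC-2w minus UASMC), and up to 4 called members of a list with the largest change.

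Each array was projected on the line from the EPC mean to the UASMC mean over the genes called between them, so that EPC lie at 0 and UASMC at 1. The iSMC groups were compared on it by a two-sided exact permutation test. Overlaps between comparisons that share the EPC arrays were set beside 50 simulated draws of unchanged groups and beside the overlap of independent lists. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

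The alternatives were the replicate number as a block, fits of only the 2 groups compared, a trended and robust variance, array weights, leaving out the dimmest 30% of genes, the mean of all probe sets of a gene, each probe set tested alone, cyclic loess, centring on ribosomal protein genes, an adjusted p under 0.01, other gene sets for the line, and leaving out each array in turn. Centring on the poly-A spike-in probe sets was added after the data were seen. Tested on simulated values for iSMC-2w minus EPC with 11914 genes, the fit recovered 24% of 50 genes changed by 0.25 log2, 86% of those changed by 0.5 and 100% of those changed by 1 or 2, among 180 calls in all, of which 14 fell on a simulated list of 30 genes moved by 0.3 and 11 were false. A simulated position of 0.6 came back as 0.6001.

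The labels call the replicates biological, but whether they are separate donors or separate cultures is not given in the sources used here, so p-values measure only the spread between these arrays. Scan dates and batches are likewise not given. The iSMC-4w samples were collected 2 weeks after the others. The induced groups alone had doxycycline and, from week 1, a smooth muscle growth medium, and the EPC were non-transduced, so these factors coincide with the groups. EPC and UASMC come from different tissues, and whether they share donors is not given.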

Results

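Gene expression was measured on 12 arrays in 4 groups of 3. Endothelial progenitor cells (EPC) from whole blood, which are proliferating cells of the endothelial lineage, served as the starting population. They were induced to express myocardin (MYOCD), a coactivator of serum response factor that drives smooth muscle genes. One group was collected after 2 weeks of induction (iSMC-2w). Another had 2 weeks of induction and then 2 weeks of culture without it (iSMC-4w). Primary umbilical smooth muscle cells (UASMC), from the artery by the series text and from the aorta by the sample titles, were the reference for the target cell type. The annotation used here lists 0 probe sets for MYOCD, so the induced gene itself was not analysed here. Pearson correlations across probe sets, which are not independent replicates, were 0.996 to 0.998 between arrays of a group. They were 0.887 to 0.888 between EPC and UASMC, and 0.974 to 0.979 between iSMC-2w and iSMC-4w.

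Control probe sets differed between groups. The poly-A spike-ins, RNAs added to the sample before amplification, had a log2 level of 9.09 ± 0.11 in EPC, 9.84 ± 0.096 in iSMC-2w, 8.71 ± 0.18 in iSMC-4w and 9.09 ± 0.16 in UASMC (mean ± SD, n = 3 arrays). The hybridisation controls, added just before hybridisation, were at 10.69 ± 0.031, 11.19 ± 0.058, 10.72 ± 0.038 and 10.93 ± 0.027 in the same order. The 3' minus 5' difference of GAPDH, a sign of RNA integrity, was 0.044 ± 0.013 log2 in EPC, 0.155 ± 0.02 in iSMC-2w, 0.046 ± 0.033 in iSMC-4w and 0.066 ± 0.035 in UASMC (mean ± SD, n = 3 arrays). Each iSMC-2w array lay above every other array, a difference that goes along with every comparison with iSMC-2w. That of ACTB was 0.91 ± 0.161 in EPC, 0.524 ± 0.153 in iSMC-2w, 0.81 ± 0.215 in iSMC-4w and 1.243 ± 0.087 in UASMC, where each array lay above every array of the other groups, a difference that goes along with every comparison with UASMC. All values below are on the deposited scale, on which the median of all genes differed by 0.03 log2 between iSMC-2w and EPC and by -0.01 between iSMC-4w and iSMC-2w. Centring each array on its poly-A spike-ins shifted all genes by -0.75 log2 in iSMC-2w minus EPC, 0.38 in iSMC-4w minus EPC and 1.13 in iSMC-4w minus iSMC-2w. It shifted iSMC-2w minus UASMC by -0.74 and iSMC-4w minus UASMC by 0.39. Centring on ribosomal protein genes shifted the comparisons with EPC by 0.36 at 2 weeks, 0.36 at 4 weeks and 0.30 in UASMC. Medians of gene lists are therefore given relative to the median of all genes. A plain median is one not set relative to all genes. Centring on poly-A spike-ins moves every plain median of a comparison by the shift above and leaves the relative ones as they are. The genes of an array then share the error of its spike-in median, so counts of calls with poly-A centring are not independent between genes. For each list the count of genes called is that over all genes tested, and the count adjusted over the list alone is added where it differs. The 3 TrpnX control probe sets, whose target is not among the spike-ins, read 3.65 to 5.20 log2, and a difference from a group mean in or below this range is a lower bound. The brightest probe set of each array read 15.13 to 15.39, so values just under it bound differences too.

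**Figure D1:**
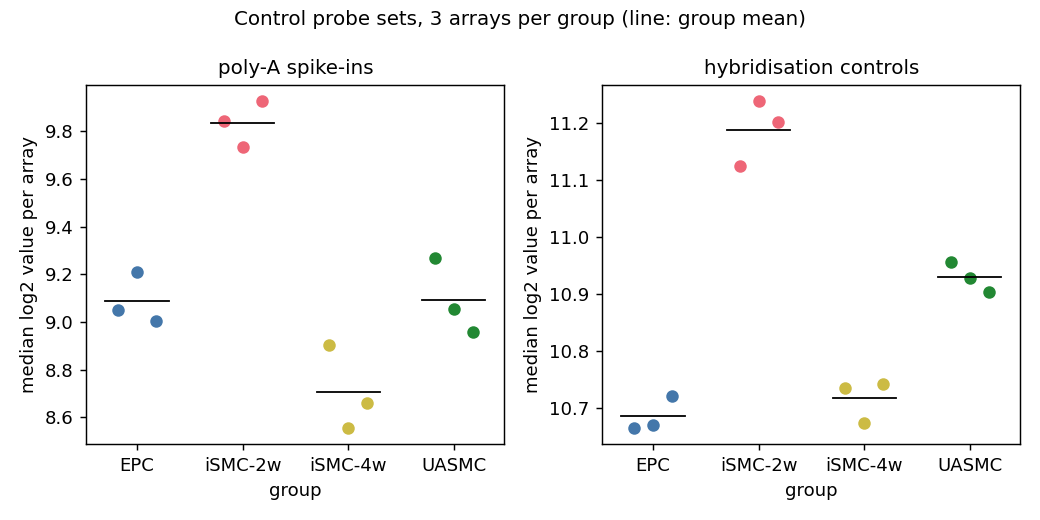
Median log2 value per array of the poly-A spike-ins (left) and the hybridisation controls (right) in the 4 groups, with a point for each of 3 arrays and a line at the group mean. The iSMC-2w arrays have the highest group mean in both panels, 9.84 and 11.19.

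The first comparison set cells after 2 weeks of MYOCD induction against EPC. Smooth muscle contractile genes rose. ACTG2, enteric smooth muscle actin, rose by 8.71 ± 0.071 log2 (SE, 3 arrays per group), phospholamban (PLN) by 8.30 ± 0.12 and myosin light chain kinase (MYLK) by 7.93 ± 0.06, with limma Benjamini-Hochberg adjusted p = 3.77e-16, 6.84e-14 and 2.3e-16. Of 26 measured contractile genes, 25 rose and 1 fell, the fall being SMTN (-0.35). The median was 1.69 log2 (camera adjusted p = 1.93e-12, and adjusted p = 0.000804 with an estimated correlation). With poly-A centring 15 were higher and 2 lower, with a plain median of 0.98 against 1.73. Genes of striated muscle rose too. The skeletal actin gene ACTA1 rose by 9.28 ± 0.16, the cardiac actin gene ACTC1 by 7.47 ± 0.086 and NPPB, which encodes B-type natriuretic peptide, by 9.33 ± 0.13. In the cardiac and skeletal sarcomere list 23 of 42 genes rose, 1 fell and 18 did not pass, with a median of 0.30, and a plain one of 0.33 that turned to -0.41 with poly-A centring (camera adjusted p = 0.000123). The tendon gene TNMD, tenomodulin, rose by 9.84 ± 0.055. Among 34 smooth muscle channel and receptor genes 16 rose and 3 fell, with a median of 0.12, and a plain one of 0.15 that turned to -0.59 with poly-A centring (camera adjusted p = 0.017, and adjusted p = 0.0935 with an estimated correlation). OXTR, the oxytocin receptor, rose by 7.39 ± 0.17 and KCNMB1, a potassium channel subunit of smooth muscle, by 4.42 ± 0.071.

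Endothelial genes fell at 2 weeks. Of 36 measured, 30 fell and 4 rose, with a median of -1.51 log2 (camera adjusted p = 1.58e-07). MMRN1 fell by 3.11 ± 0.11 and VWF, von Willebrand factor, fell by 2.88 ± 0.15, while the adhesion receptor SELE rose by 1.68 ± 0.13. All 50 measured cell cycle genes fell, with a median of -4.31 (camera adjusted p = 7.83e-25). TOP2A, DNA topoisomerase of dividing cells, fell by 5.88 ± 0.13 and the kinetochore gene NDC80 fell by 6.01 ± 0.15. In the list of p53 targets, cell-cycle inhibitors and secretory senescence genes 11 of 18 rose and 4 fell (camera adjusted p = 0.0135, and adjusted p = 0.0577 with an estimated correlation), and the median was 0.62, and the plain one of 0.66 turned to -0.09 with poly-A centring. IGFBP3 rose by 6.12 ± 0.045, and LMNB1, a nuclear lamin, fell by 4.95 ± 0.099.

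Matrix and signalling genes also moved at 2 weeks. Among 45 fibrillar matrix and elastic fibre genes 29 rose and 2 fell, with a median of 0.54, and a plain one of 0.58 that turned to -0.17 with poly-A centring (camera adjusted p = 7.06e-08, and adjusted p = 0.0577 with an estimated correlation). Periostin (POSTN) rose by 4.84 ± 0.15 and tenascin C (TNC) by 4.21 ± 0.15. In the basement membrane list 15 of 21 rose and 1 fell, with a median of 0.65, and a plain one of 0.68 against -0.07 with poly-A centring (camera adjusted p = 0.000334, and adjusted p = 0.193 with an estimated correlation). The TGF-beta response list had 22 of 30 genes higher and 5 lower, with a median of 0.56, and a plain one of 0.59 against -0.15 with poly-A centring (camera adjusted p = 0.000566), and its genes ID2 and INHBA rose by 5.33 and 4.86 while BMP4 fell by 2.48. Of 30 NF-kB and inflammatory cytokine genes 19 rose and 4 fell, or 20 and 4 adjusted over the list alone, with a median of 1.09 (with poly-A centring 15 higher and 12 lower, plain median 0.37 against 1.12; camera adjusted p = 0.000566, and adjusted p = 0.0738 with an estimated correlation). The alarmin IL33 rose by 5.01 ± 0.16 and the chemokine CXCL6 fell by 3.64 ± 0.16. Among fibroblast and pericyte genes, whose list was not called (camera adjusted p = 0.081), IGFBP5 rose by 6.78 ± 0.097, FAP rose by 6.21 ± 0.11 and the homeobox gene MEOX2 fell by 5.70 ± 0.093.

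In all, 7809 of 11914 genes were called at 2 weeks against EPC, 3862 higher and 3947 lower, and 2220 of them changed at least 2-fold. The split was 7726 higher and 2378 lower with ribosomal centring, and 909 higher and 9690 lower with poly-A centring. The 3 arrays of a group limit the precision. Medium and doxycycline differed along with MYOCD induction, and the EPC were non-transduced, so the effect of MYOCD alone cannot be told apart from these.

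**Figure D2:**
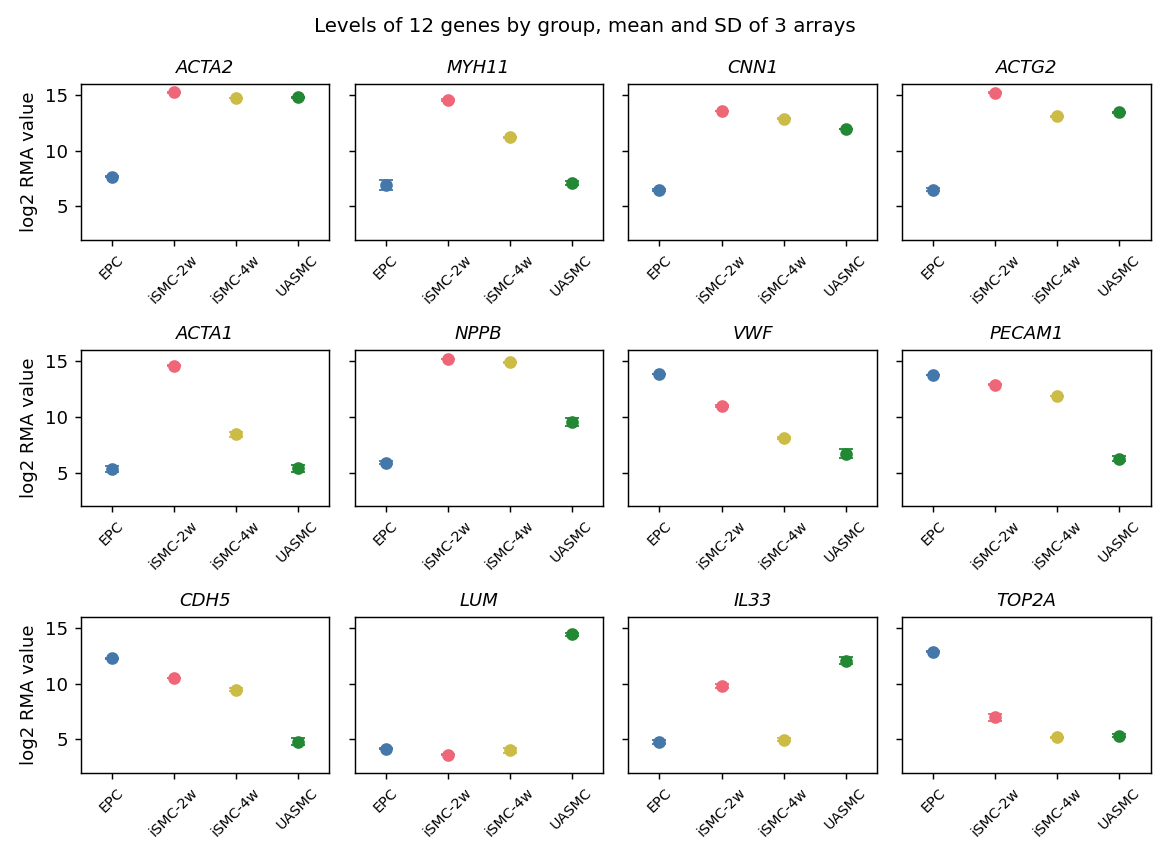
Log2 RMA values (y axis) of 12 genes in the 4 groups (x axis), shown as the mean with bars for the SD of 3 arrays. ACTA2 has means of 7.67 in EPC, 15.22 in iSMC-2w, 14.74 in iSMC-4w and 14.76 in UASMC, and LUM has 4.16, 3.61, 4.00 and 14.40.

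The second comparison set iSMC-4w, 2 weeks after induction ended, against EPC. Smooth muscle contractile genes were still above their level in EPC. ACTA2, smooth muscle alpha-actin, was higher by 7.07 ± 0.044 log2 (SE, 3 arrays per group, limma adjusted p = 7.64e-17), ACTG2 by 6.58 ± 0.071 and calponin (CNN1) by 6.40 ± 0.06. Of 26 contractile genes 20 rose, 2 fell and 4 did not pass, with a median of 0.85 (camera adjusted p = 5.4e-08). OXTR was higher by 7.99 ± 0.17 and the sarcomere gene ACTC1 by 4.56 ± 0.086, but their lists, called at 2 weeks, were not called at 4. Of 34 smooth muscle channel and receptor genes 12 were higher, 3 lower and 19 did not pass, or 26 higher and 1 lower with poly-A centring (median 0.05, camera adjusted p = 0.0885). Of 42 sarcomere genes 14 were higher, 1 lower and 27 did not pass, or 32 higher and 0 lower with poly-A centring (median 0.08, camera adjusted p = 0.058). Endothelial genes stood lower than in EPC in 31 of 36 cases and higher in 3, with a median of -1.76 (camera adjusted p = 1.25e-11). VWF fell by 5.73 ± 0.15 and MMRN1 fell by 5.80 ± 0.11, while THBD, thrombomodulin, rose by 2.46 ± 0.18.

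All 50 cell cycle genes were below EPC at 4 weeks, with a median of -4.17 (camera adjusted p = 5.28e-32). RRM2, a ribonucleotide reductase subunit, fell by 7.28 ± 0.14 and CDK1 fell by 6.94 ± 0.13. In the p53 and senescence list 11 of 18 genes rose and 2 fell (camera adjusted p = 0.00472), with IGFBP3 higher by 6.24 and the inhibitor CDKN2A higher by 2.55. Fibrillar matrix genes rose in 30 of 45 cases and fell in 3, with a median of 0.52 (camera adjusted p = 3.91e-06, and adjusted p = 0.114 with an estimated correlation). POSTN rose by 4.93 ± 0.15 and the crosslinking enzyme LOX rose by 2.79 ± 0.056. The NF-kB list had 12 genes higher and 10 lower of 30 and was not called (camera adjusted p = 0.798), with 16 higher and 7 lower with poly-A centring. Its plain median of 0.08 and its mean of -0.33 differed in sign.

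Between 4 weeks and EPC 6740 genes were called, 3491 higher and 3249 lower, and 1683 changed at least 2-fold. The split became 8259 higher and 1724 lower with ribosomal centring, and 7273 and 1327 with poly-A centring.

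The third comparison asked what changed between the end of induction and 2 weeks later. Contractile genes were lower at 4 weeks than at 2 on the deposited scale. Of 26 measured, 22 fell and 4 did not pass, with a median of -0.59 log2, and a plain one of -0.59 that turned to 0.53 with poly-A centring (camera adjusted p = 1.07e-10, and adjusted p = 0.00127 with an estimated correlation). MYH11, smooth muscle myosin heavy chain, fell by 3.36 ± 0.17, PPP1R12B, a myosin phosphatase subunit, fell by 3.51 ± 0.099 and MYLK fell by 2.82 ± 0.06 (SE, 3 arrays per group). With poly-A centring 15 of the 26 contractile genes were called higher and 8 lower. The 8 are all among the 22 above, with MYH11 at -2.24 and PPP1R12B at -2.38. ACTA2 was then at 0.65, but its iSMC-2w level lay near the array maximum, which limits what this value shows. Striated muscle genes fell as well on the deposited scale. The sarcomere list had 15 of 42 lower and 2 higher, or 14 and 2 adjusted over the list alone, with a median of -0.16, and a plain one of -0.17 against 0.96 with poly-A centring (camera adjusted p = 0.000163). ACTA1 fell by 6.15 ± 0.16 and TTN, titin, fell by 3.32 ± 0.078. The poly-A spike-ins were higher at 2 weeks than at 4 by 1.13 log2.

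Inflammatory genes were lower at 4 weeks on the deposited scale. Of 30 NF-kB and cytokine genes 23 fell and 2 rose, with a median of -1.22 log2 (camera adjusted p = 1.72e-09). With poly-A centring 14 fell and 14 rose, with a plain median of -0.10 against -1.23. IL33 fell by 4.81 ± 0.16, NFKBIA, the NF-kB inhibitor, fell by 3.39 ± 0.079, and TNFAIP6 rose by 1.60 ± 0.14. The endothelial list fell further on the deposited scale, 22 of 36 lower and 7 higher, or 24 and 7 adjusted over the list alone, with a median of -0.40, and a plain one of -0.41 against 0.72 with poly-A centring (camera adjusted p = 0.000577). VWF fell by 2.86 ± 0.15 while THBD rose by 1.05 ± 0.18. Basement membrane genes fell in 10 of 21 cases and rose in 2, or 12 and 2 adjusted over the list alone, with a median of -0.19, and a plain one of -0.20 against 0.93 with poly-A centring (camera adjusted p = 0.0019, and adjusted p = 0.299 with an estimated correlation). The laminin gene LAMA4 fell by 2.39 ± 0.098 and NID1, nidogen, fell by 1.85 ± 0.086. Fibrillar matrix genes fell in 21 of 45 cases and rose in 5, with a median of -0.14, and a plain one of -0.15 against 0.98 with poly-A centring (camera adjusted p = 0.000577, and adjusted p = 0.226 with an estimated correlation). Elsewhere the retinoid isomerase gene RPE65 fell by 7.15 ± 0.15 and the chemokine CXCL14 fell by 6.38 ± 0.11, while AOX1, aldehyde oxidase, rose by 3.84 ± 0.11 and TNFRSF11B, osteoprotegerin, rose by 3.56 ± 0.12.

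Stress and growth response genes fell between 2 and 4 weeks on the deposited scale. In the ATF4 and unfolded protein response list 24 of 38 genes fell and 7 rose, with a median of -0.44, and a plain one of -0.45 against 0.68 with poly-A centring (camera adjusted p = 2.35e-05, and adjusted p = 0.123 with an estimated correlation). DDIT4, an inhibitor of mTOR signalling, fell by 4.49 ± 0.17 and the amino acid transporter SLC7A5 fell by 1.72 ± 0.084. The serum response immediate early list had 12 of 20 genes lower and 1 higher, with a median of -0.62, and a plain one of -0.63 against 0.50 with poly-A centring (camera adjusted p = 0.00481, and adjusted p = 0.58 with an estimated correlation), and ZFP36, which destabilises cytokine mRNA, fell by 3.04 ± 0.23. In the Notch and arterial-venous list 8 of 17 genes fell and 9 did not pass, with a median of -0.20, and a plain one of -0.21 against 0.92 with poly-A centring (camera adjusted p = 0.00661, and adjusted p = 0.196 with an estimated correlation). The neuropilin gene NRP1 fell by 2.39 ± 0.12 and the Notch target HES1 fell by 1.86 ± 0.47. Nuclear genes of the respiratory chain rose in 26 of 51 cases and fell in 3, with a median of 0.13, and a plain one of 0.12 against -0.01 with cyclic loess (camera adjusted p = 0.0102, adjusted p = 0.524 with an estimated correlation, and 0.0811 with dim genes left out). NDUFC1, a complex I subunit, rose by 0.56 ± 0.05.

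Cell cycle genes, already low at 2 weeks, fell in 30 of 50 cases and rose in 8, with a median of -0.35, and a plain one of -0.36 against 0.77 with poly-A centring (camera adjusted p = 0.000577, and adjusted p = 0.226 with an estimated correlation). Of 6335 genes called, 3594 were higher and 2741 lower at 4 weeks, and 788 changed at least 2-fold, 389 higher and 399 lower. With poly-A centring the calls were 11380 higher and 200 lower, and the 2-fold changes were 283 higher and 465 lower with cyclic loess.

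The fourth comparison, UASMC against EPC, set the distance between target and starting cell types. Fibrillar matrix genes were higher in UASMC in 39 of 45 cases and lower in 3, with a median of 2.75 log2 (camera adjusted p = 3.33e-15). The collagen-binding proteoglycan LUM was higher by at least 10.24 ± 0.097 (SE, 3 arrays per group), with an EPC level within the TrpnX range, the matricellular gene THBS2, likewise in that range in EPC, by at least 8.69 ± 0.089, and decorin (DCN) by 7.97 ± 0.12. Contractile genes were higher in 18 of 26 cases and lower in 5 (median 0.67, camera adjusted p = 9.05e-05), with ACTA2 higher by 7.09 ± 0.044. Endothelial genes were lower in 34 of 36 cases (median -3.64, camera adjusted p = 3.33e-15), led by MMRN1 at -8.76 ± 0.11 and PECAM1 at -7.51 ± 0.093. All 50 cell cycle genes were lower (median -4.69, camera adjusted p = 1.29e-24). NF-kB and cytokine genes were higher in 26 of 30 cases (median 2.00, camera adjusted p = 9.77e-08), with IL33 at 7.30 ± 0.16 and the cyclooxygenase gene PTGS2 at 6.68 ± 0.10. Fibroblast and pericyte genes were higher in 16 of 26 cases and lower in 5 (median 1.10, camera adjusted p = 0.000545). Of 7542 genes called, 3565 were higher and 3977 lower in UASMC, or 6980 higher and 2524 lower with ribosomal centring.

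**Figure D3:**
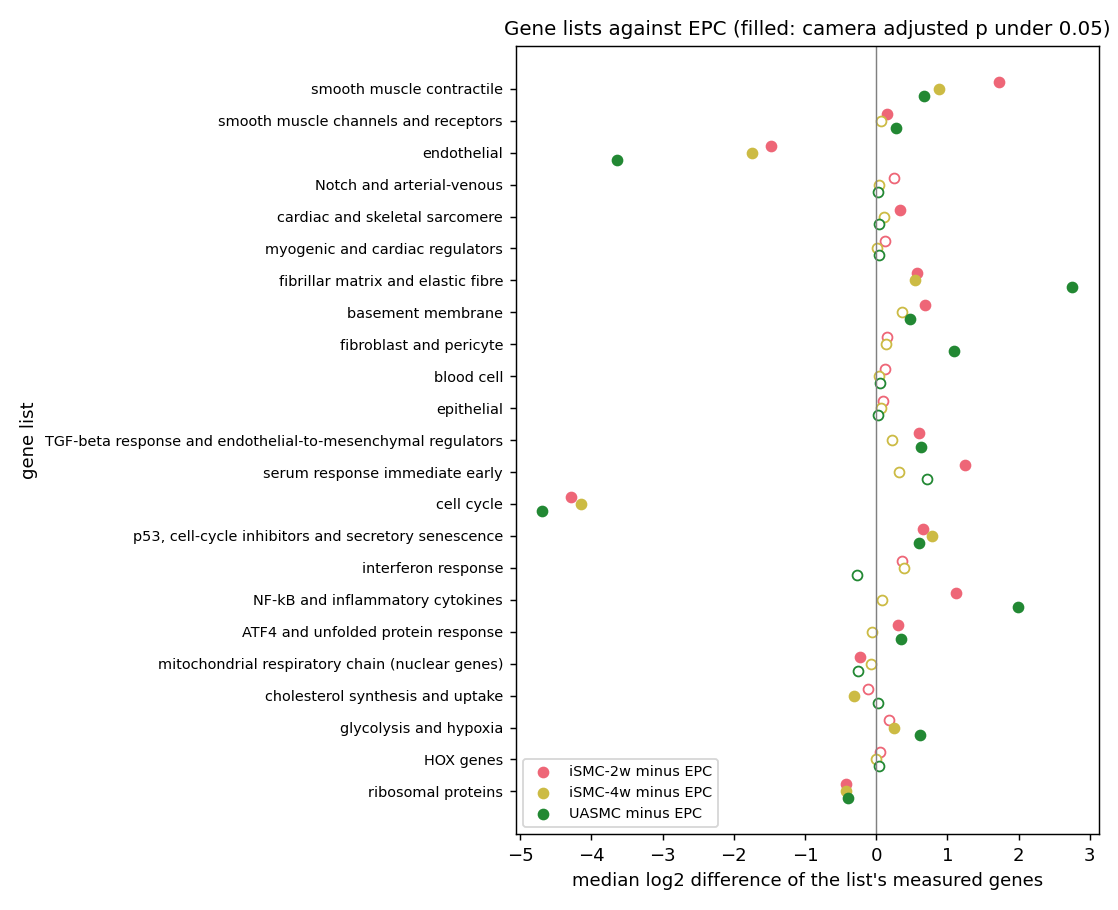
Median log2 difference (x axis) of the measured genes of each of 23 fixed gene lists (y axis) in iSMC-2w, iSMC-4w and UASMC, each minus EPC, with filled points for lists called by camera at an adjusted p under 0.05 and open points for the others, on the deposited scale. The cell cycle list lies at -4.28, -4.14 and -4.69, and the fibrillar matrix list at 0.58, 0.54 and 2.75, all plain medians, the first of the matrix list turning to -0.17 with arrays centred on poly-A spike-ins.

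The fifth comparison set iSMC-2w beside UASMC. Contractile genes were higher in iSMC-2w in 23 of 26 cases and lower in 2, with a median of 0.99 log2 (camera adjusted p = 1.92e-07). With poly-A centring 13 were higher and 5 lower, with a plain median of 0.29 against 1.03. MYH11 was higher by 7.46 ± 0.17 (SE, 3 arrays per group) and PLN by 3.99 ± 0.12, while HSPB6, a small heat shock protein of muscle, was lower at -2.34 ± 0.11. Endothelial genes were higher in 31 of 36 cases and lower in 3 (median 2.25, camera adjusted p = 9.36e-11), or 23 and 6 with poly-A centring, with PECAM1 higher by 6.62 ± 0.093. Fibrillar matrix genes were lower in 30 of 45 cases and higher in 8, or 30 and 11 adjusted over the list alone, with a median of -1.12 (camera adjusted p = 1.56e-06, and adjusted p = 0.0937 with an estimated correlation). LUM, below the TrpnX range in iSMC-2w, was lower there at -10.79 ± 0.097, a lower bound in size. Sarcomere genes were higher in 23 of 42 cases, with a median of 0.19, and a plain one of 0.23 against -0.51 with poly-A centring (camera adjusted p = 0.000389), and ACTA1 was higher by 9.24 ± 0.16. In all 7146 genes were called, 3656 higher and 3490 lower in iSMC-2w, or 804 higher and 9873 lower with poly-A centring.

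The sixth comparison set iSMC-4w beside UASMC. Contractile genes went both ways, 12 of 26 higher and 8 lower in iSMC-4w, or 12 and 9 adjusted over the list alone, and the list was not called (camera adjusted p = 0.471), with a median of 0.03, and a plain one of 0.06 that turned to -0.03 with cyclic loess. With poly-A centring 17 were higher and 3 lower, with a plain median of 0.45 against 0.06. ACTA2 had 14.74 ± 0.015 in iSMC-4w and 14.76 ± 0.027 in UASMC (mean ± SD, n = 3 arrays, limma adjusted p = 0.766), both near the array maximum, where nearly equal values do not show equal expression. MYH11 was higher in iSMC-4w by 4.09 ± 0.17. Endothelial genes were higher in 25 of 36 cases and lower in 1, or 26 and 1 adjusted over the list alone (median 1.31, camera adjusted p = 7.24e-09), among them THBD at 6.82 ± 0.18 and the transcription factor TAL1 at 6.11 ± 0.098. Fibrillar matrix genes were lower in 31 of 45 cases and higher in 8, or 32 and 8 adjusted over the list alone (median -1.48, camera adjusted p = 1.07e-11). LUM and THBS2, within the TrpnX range in iSMC-4w, were lower there at -10.40 ± 0.097 and -8.70 ± 0.089, both lower bounds in size. The elastin gene ELN was higher in iSMC-4w by 2.14 ± 0.12. NF-kB and cytokine genes were lower in 24 of 30 cases (median -2.23, camera adjusted p = 1.07e-11), or 22 with 6 higher with poly-A centring, with CXCL6 at -8.04 ± 0.16 and IL33 at -7.09 ± 0.16. Fibroblast and pericyte genes were lower in 14 of 26 cases and higher in 5, with a median of -0.24, and a plain one of -0.21 that turned to 0.18 with poly-A centring (camera adjusted p = 0.000353), and THY1, a fibroblast surface protein, was lower at -6.92 ± 0.077. In all 6133 genes were called, 3649 higher and 2484 lower in iSMC-4w, or 7771 higher and 983 lower with poly-A centring.

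The induced cells were then placed between EPC and UASMC. On the line from the EPC mean (0) to the UASMC mean (1) over the 7542 genes that differ between them, iSMC-2w lay at 0.493 ± 0.0041 and iSMC-4w at 0.486 ± 0.0003 (mean ± SD, n = 3 arrays). A two-sided exact permutation test between them gave p = 0.1, the smallest that 3 against 3 arrays allow. The root mean square distance from this line was 0.94 ± 0.019 log2 in iSMC-2w and 0.833 ± 0.005 in iSMC-4w, beside 0.796 and 0.785 along it. Gene lists differed in position. Contractile genes lay at 1.17 ± 0.004 in iSMC-2w and 0.884 ± 0.008 in iSMC-4w, endothelial genes at 0.278 ± 0.004 and 0.436 ± 0.006, and fibrillar matrix genes at 0.253 ± 0.001 and 0.182 ± 0.008. NF-kB and cytokine genes lay at 0.347 ± 0.005 and 0.049 ± 0.005, and cell cycle genes at 0.849 ± 0.022 and 0.953 ± 0.003. With poly-A centring the order of the 2 times reversed for endothelial genes (0.422 and 0.362), fibrillar matrix genes (0.123 and 0.248) and cell cycle genes (0.994 and 0.878), while contractile genes lay at 1.036 and 0.953 and NF-kB genes at 0.185 and 0.133.

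**Figure D4:**
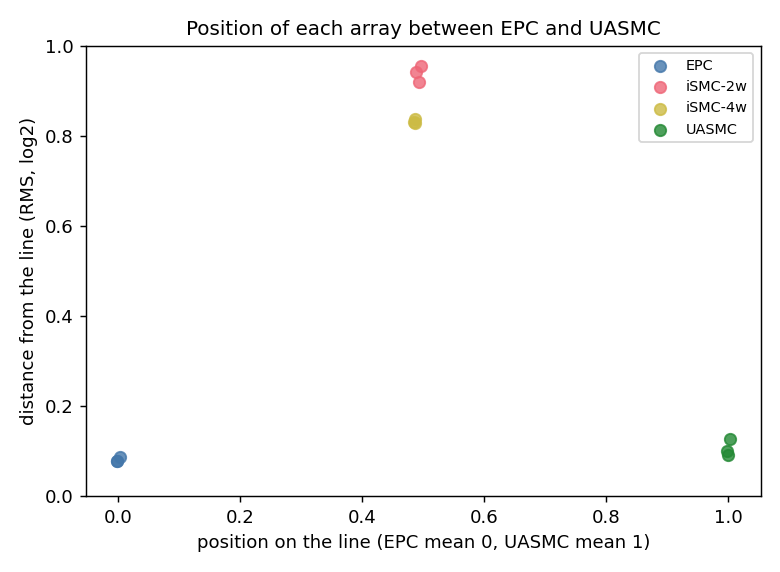
Position of each of 12 arrays on the line from the EPC mean (0) to the UASMC mean (1) (x axis) against its root mean square distance from that line in log2 (y axis), with a point per array coloured by group. The iSMC-2w arrays average 0.493 on the line and 0.94 off it, and the iSMC-4w arrays 0.486 and 0.833.

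Gene by gene, 5089 genes were called the same way in iSMC-2w and UASMC against EPC, 2240 higher and 2849 lower, and 929 opposite ways. For iSMC-4w the same-way count was 4866, 2250 higher and 2616 lower, and 768 went opposite ways. Independent lists of these sizes would share 1156 and 1318 genes at 2 weeks and 1045 and 1085 at 4 weeks. In 50 simulations of unchanged groups sharing the EPC arrays the mean same-way count was 0 in both cases. The covariance of the log2 differences across genes was 0.818 at 2 weeks and 0.807 at 4 weeks, against 0.0042 in the simulations. The Pearson correlation across genes was 0.613 and 0.668, against 0.5 and 0.497 simulated. The simulated correlation is that of spread between arrays alone, so it does not measure how much of the observed one is spread. Unchanged groups give almost no calls, so the simulated count of 0 is no measure of how far called genes overlap. The simulated covariance of 0.0042 argues against spread of the shared EPC arrays as the main source of the observed covariance. Anything that all EPC arrays have in common was not simulated, so its part stays open.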

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

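The gene and list calls in this part were planned, and the tests of explanations, the other splits and poly-A centring were chosen after the result was seen. The first group of results below stands out because a list differed between iSMC-4w and iSMC-2w by camera, that is, it had moved from EPC by a different amount at 4 weeks than at 2. The plain medians, not set relative to all genes, were in log2 -0.5947 for contractile, -0.4109 for endothelial, -0.2108 for Notch and arterial-venous, -0.1652 for sarcomere, -0.1502 for fibrillar matrix, -0.2031 for basement membrane, -0.6291 for immediate early and -0.3609 for cell cycle genes. They were -1.229 for NF-kB and cytokine genes, -0.4468 for ATF4 and unfolded protein response genes and 0.1225 for respiratory chain genes. With an estimated correlation the call was lost for 7 of the 11 lists, with adjusted p = 0.196 for Notch, 0.226 for fibrillar matrix, 0.299 for basement membrane, 0.58 for immediate early, 0.226 for cell cycle, 0.123 for ATF4 and 0.524 for respiratory chain genes. Centring on the poly-A spike-ins adds 1.128 log2 to every gene here, so that alone puts all these medians but that of the NF-kB genes above 0 and does not change how a list moved against other genes, and with cyclic loess the respiratory chain median fell below 0. In the NF-kB list 14 of 30 genes were called lower and 14 higher at 4 weeks with poly-A centring, with a median of -0.101. Another 515 genes stand out because they were called in opposite directions from EPC at 2 and 4 weeks and different between them, 132 higher and then lower and 383 lower and then higher. Of these, 6 moved at least 2-fold both ways, RAPGEF5, CXCL2, RGCC, MAP3K8, PRR16 and MID1IP1, named after their values were seen, with RAPGEF5 at 1.29 and then -2.50. Many more genes, 5170, were called the same way from EPC at both times. Independent lists of these sizes would give 2210 opposite ways, so the 515 are fewer than that. Poly-A centring shifts the 2-week comparison with EPC by -0.746 and the 4-week one by 0.382, so the sign of small changes depends on the scaling. The control probe sets stand out because they lie outside the main measurement and were above their level in EPC, with poly-A spike-ins at 0.746 log2 and hybridisation controls at 0.503 in iSMC-2w minus EPC.

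The first pattern weighed is the high poly-A spike-in signal in iSMC-2w. Poly-A spike-ins minus hybridisation controls was 0.656 log2 higher in iSMC-2w than in iSMC-4w (SE 0.1169) and 0.2428 higher than in EPC (SE 0.1052). The second was only about 2 SE from 0 with 3 arrays per group. Poly-A spike-ins pass through amplification with the sample and hybridisation controls do not. Dimmer arrays for sample RNA need not raise both alike, so this difference cannot decide on them and they stay open. Degraded RNA would raise the 3' minus 5' differences, which in iSMC-2w lay 0.103 log2 above the mean of the other groups for GAPDH and at -0.4634 for ACTB. The ACTB 3' probe set read 14.97 to 15.03 in iSMC-2w, near the array maximum, which limits what the ACTB value shows. Between iSMC-2w and iSMC-4w the poly-A spike-ins differed by 1.128 log2 and the hybridisation controls by 0.472. Against EPC, poly-A spike-ins minus hybridisation controls stood at 0.243 in iSMC-2w, -0.413 in iSMC-4w and -0.239 in UASMC. The 0.656 thus comes from both induced groups, and more from iSMC-4w. Differences in polyadenylated RNA per amount of total RNA or in RNA per amount of spike-in may underlie these values. The 2 cannot be told apart because the amounts of RNA and spike-in are not given.

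The second pattern is the lower level of contractile genes at 4 weeks than at 2. Growth of uninduced EPC-like cells would need a share of 77.19% and would raise the 30 endothelial genes that had fallen by 2 weeks by a median of 1.306 log2, but on the deposited scale their median change was -0.3735, with 18 called lower again and 6 higher. With poly-A centring the median was 0.7543 (SE 0.2133) against the 1.884 that a share of 69.42% would need. Cells dividing like EPC at that share would hold the 50 cell cycle genes at -0.5267 or more in iSMC-4w minus EPC. Their median was -3.762 (SE 0.2834), all called lower. The cell cycle test replaced one asking for an endothelial median under 0 after its value was seen. On both scales the values argue against growth of cells that kept the EPC profile as the whole cause. Uninduced cells in the smooth muscle growth medium were not measured. Growth of cells that changed in that medium, or that had stopped dividing by 4 weeks, stays open. Scaling between arrays as the whole cause is argued against for 8 genes still called lower with poly-A centring, ACTG2, CSRP1, ITGA1, LPP, MYH11, MYLK, PLN and PPP1R12B. All genes share the error of the 1.128 log2 shift, with spike-in SDs of 0.096 in iSMC-2w and 0.179 in iSMC-4w (n = 3 arrays). These calls are thus not independent, and those of CSRP1 at -0.464 and LPP at -0.491 are the least secure of the 8. Of the other 14 of the 22, all but ITGA5, LMOD1 and MYL9 were called higher with poly-A centring, from CNN1 at 0.446 to TAGLN at 0.972. For these 14, scaling and a real fall cannot be told apart, since the amounts of RNA and spike-in are not given. The end of MYOCD induction, which the design names, stays open as untested. So do the removal of doxycycline itself, the later collection and 2 more weeks of culture, which coincide with it.

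The third pattern is that endothelial genes stayed above UASMC at 4 weeks. Unconverted EPC that kept the EPC profile would hold all endothelial genes at 1 share. The 24 genes other than VWF had a median of 26.25% of the EPC level, while VWF had 1.884% and MMRN1 1.797%. THBD at 550.7%, TAL1 at 136.7% and MCAM at 125.6% were above EPC itself. Of the 24, 22 exceeded 3 times the share of VWF, or 91.67% against a mark of 90% that was written after the values were seen, and among the 18 with an EPC mean over 10 log2, a restriction tried after that result, 16 did, or 88.89%, just short of it. Apart from that mark, levels from under 2% to over 100% of EPC argue against unconverted EPC that kept the EPC profile as the whole cause. A small share of them beside other cells stays open. Uninduced EPC in doxycycline and the smooth muscle growth medium were not measured, so unconverted EPC whose endothelial genes changed there stay open too. Endothelial expression kept in induced cells could account for the 22 genes, but cells were not measured one by one, so this stays open.

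Other groupings of the same arrays were also tried. For each comparison the 6 arrays allow 10 splits, so a share under 0.05 cannot be reached. As many genes as in the real split were called in 1 of the 10 splits, the real one, in each comparison: 7809 in iSMC-2w minus EPC, 6740 in iSMC-4w minus EPC, 7542 in UASMC minus EPC, 6335 in iSMC-4w minus iSMC-2w, 7146 in iSMC-2w minus UASMC and 6133 in iSMC-4w minus UASMC. The highest other split gave 0 by limma in each, with 377, 202, 279, 677, 689 and 329 genes at an unadjusted p under 0.05. Each other split mixes arrays of both groups, so the difference between the groups enters the residual spread, which alone makes few calls likely. Part of that difference also stays between the mixed groups. Their counts of genes, and of lists below, are therefore no measure of chance. As many lists by camera as in the real split were called in 1, 2, 2, 1, 4 and 2 of the 10 splits in the same order, with 14, 8, 13, 11, 9 and 9 lists in the real split and 13, 8, 14, 9, 9 and 10 in the highest other.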

How the results depend on the processing

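Centring on poly-A spike-ins was chosen after seeing the data, and the other alternatives before the data were examined. With each probe set tested alone, the counts were 11879 in iSMC-2w minus EPC, 10119 in iSMC-4w minus EPC, 11366 in UASMC minus EPC, 10811 in iSMC-2w minus UASMC and 9216 in iSMC-4w minus UASMC, because more features are tested. The counts at 2-fold or more were then 1208 in iSMC-4w minus iSMC-2w, 2619 in iSMC-2w minus UASMC and 2102 in iSMC-4w minus UASMC, against 788, 1708 and 1387. With poly-A centring, which shifts every gene of an array alike, iSMC-4w minus iSMC-2w had 11580 genes called and 8025 at 2-fold or more, and the 2-fold counts were 4048 in iSMC-2w minus EPC and 3443 in iSMC-2w minus UASMC. Lists called with an estimated correlation were 5, 4, 6, 4, 4 and 4 of 23 (iSMC-2w, iSMC-4w and UASMC minus EPC, iSMC-4w minus iSMC-2w, then iSMC-2w and iSMC-4w minus UASMC), and with fry 22, 21, 21, 18, 20 and 20, against 14, 8, 13, 11, 9 and 9. The position of iSMC-2w was 0.4771 without the marker lists and 0.4701 without the cell cycle list. That of iSMC-4w was 0.4636 and 0.4564, 0.4862 over all genes and 0.4865 with cyclic loess, and the cause was not tested. Leaving out 1 array gave 0.4906 to 0.4946 for iSMC-2w and 0.4826 to 0.4873 for iSMC-4w, and counts of 7380 to 7919, 6337 to 6932, 7121 to 7713, 5616 to 6484, 6708 to 7145 and 5676 to 6338 genes in the order above. With the mean of all probe sets RPLP2 turned to -0.022 in iSMC-2w minus EPC (limma adjusted p = 0.83) and FBN2 to -0.481 in iSMC-4w minus iSMC-2w (adjusted p = 0.0438), since their probe sets differ. With the replicate block the counts were 7743, 6676, 7465, 6220, 7081 and 6027. Deviations from the group mean in the 18 same-numbered pairs correlated at -0.151 to 0.047, with 0 over 0.1, so no sign of something shared by number was seen. Such deviations cannot show what all arrays of a group share. Whether a number stands for a donor or a batch stays open. Of 64 list calls, the estimated correlation ended 37, leaving out dim genes 7 and the mean of probe sets 3. With 1 array left out, 73 results of named genes lost the call and 6863 kept it.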

Other observations

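The gene and list calls in this part were planned, and the tests of the 2 hypotheses were chosen after the result was seen. HOX genes, which encode position along the body axis, differed between UASMC and EPC in both directions. HOXC10 was higher in UASMC than in EPC by 5.01 ± 0.16 log2 and HOXD11 by 3.55 ± 0.087 (SE, 3 arrays per group), while HOXD1 fell by 2.18 ± 0.08. Of 22 HOX genes 10 were higher in UASMC than in EPC and 9 lower, or 12 and 6 with ribosomal centring, and the list was not called (camera adjusted p = 0.517). In iSMC-4w minus EPC 5 were higher and 5 lower, or 5 and 4 adjusted over the list alone and 12 and 4 with poly-A centring, and HOXC6 fell by 2.92 ± 0.09. Glycolysis and hypoxia genes were higher in UASMC than in EPC in 24 of 31 cases and lower in 4, with a median of 0.62 (camera adjusted p = 1.46e-05, and adjusted p = 0.112 with an estimated correlation). The glucose transporter gene SLC2A3 was higher by 2.91 ± 0.089 and VEGFA by 2.97 ± 0.11. In iSMC-2w, VEGFA was higher than in EPC by 2.78 ± 0.11. Cholesterol synthesis genes were lower in iSMC-2w than in UASMC in 16 of 24 cases and higher in 1 (median -0.39, camera adjusted p = 0.00164), with FADS2 at -1.50 ± 0.081. Ribosomal protein genes were lower in iSMC-2w than in EPC in 48 of 51 cases and higher in 1 (median -0.46, camera adjusted p = 1.1e-09, and adjusted p = 0.13 with an estimated correlation), with RPS9 at -1.03 ± 0.049.

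Interferon response genes were higher in iSMC-2w than in UASMC in 26 of 43 cases and lower in 9, or 26 and 10 adjusted over the list alone. Their median was 0.57, and the plain one of 0.61 turned to -0.13 with poly-A centring (camera adjusted p = 0.0228, adjusted p = 0.796 with an estimated correlation, and 0.0524 with the mean of probe sets). IFI27 was higher in iSMC-2w by 8.67 ± 0.19 and BST2, tetherin, by 4.09 ± 0.13. Epithelial genes included DSP, desmoplakin, which rose by 5.94 ± 0.16 in iSMC-4w minus EPC, and KRT7, a keratin, which was higher in iSMC-4w than in UASMC by 6.01 ± 0.069. The epithelial list had 4 genes higher and 4 lower of 22 in iSMC-4w minus EPC, or 17 and 2 with poly-A centring, and was not called (camera adjusted p = 0.627). The blood cell list was not called either (camera adjusted p = 0.473 in UASMC minus EPC), with 5 of 24 genes higher and 1 lower, or 3 and 1 adjusted over the list alone. With ribosomal centring 22 were higher and 1 lower. Its plain median of 0.05 and its mean of -0.073 differed in sign, and its fall was LAPTM5 at -4.74 ± 0.12. Myogenic and cardiac regulators went both ways in UASMC minus EPC, 10 of 29 higher and 9 lower, or 20 and 7 with ribosomal centring (camera adjusted p = 0.539), with TBX2 at 4.13 ± 0.082 and TCF21 at 3.25 ± 0.14. In iSMC-2w minus EPC TEAD3 rose by 1.59 ± 0.079 and MRTFB, a myocardin-related coactivator, fell by 2.16 ± 0.16.

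The first hypothesis was that cells went on toward UASMC between 2 and 4 weeks. The Pearson correlation across genes, which are not independent replicates, of iSMC-4w minus iSMC-2w with UASMC minus EPC, comparisons that share no arrays, was -0.016, a value that centring the arrays does not change, and -0.012 with cyclic loess. Genes called in both went the same way in 2090 cases and opposite ways in 2747 on the deposited scale, where independent lists would give 1075 both higher, 915 both lower and 2020 opposite, and in 2468 and 3082 with poly-A centring. Yet each iSMC-4w array correlated more with the UASMC arrays (0.9326 to 0.9352 across probe sets) than any iSMC-2w array did (0.9177 to 0.9227). It also correlated more with EPC, at 0.9426 to 0.9436 against 0.9251 to 0.9297. The distance from the line between EPC and UASMC was 0.833 log2 against 0.94 at 2 weeks. The position on that line was 0.4858 at 4 weeks and 0.4925 at 2. These values argue against a net move along the line, and the greater likeness to UASMC came with a greater likeness to EPC. The criterion for the hypothesis was widened once, which turned its outcome from against to open, and by it the hypothesis stays open.

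The second hypothesis was that HOX genes keep the positional identity of the starting cells. Over the 19 HOX genes called between UASMC and EPC, iSMC-4w lay at -0.04715 on the line from EPC (0) to UASMC (1). In 10000 random sets of 19 other genes with a like size of change the median position was 0.5162, with 95% between 0.173 and 0.8687 (one-sided permutation p = 2e-04). HOX genes regulate one another and are not independent, and EPC and UASMC come from different tissues. The test shows no net move of these genes toward UASMC, and not what lies behind that. A position does not see changes off the line. Of 22 HOX genes 5 were called higher and 5 lower in iSMC-4w than in EPC, so not all stayed at EPC levels.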
